A study of Arabidopsis thaliana with 20 samples.

How the data were processed

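RNA from GFP-negative cells, sorted from protoplasted root sections labelled meristematic zone or elongation zone, was sequenced at 3, 4, 5, 6 and 7 days of age with 2 biological replicates per zone and age. Total RNA was extracted with a column kit and made into cDNA and libraries with low input kits, per the labels. Columella cells, which carry the GFP reporter, were left out by the sort. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.1.1 and TAIR10 were used by the authors, with neither roles nor settings stated. The deposited table holds FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for 33201 genes and 20 libraries, as made by the authors. No scaling between libraries, no filter and no combination of isoforms is stated. Column sums ran from 699298 to 833055 FPKM.

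Identifiers were matched by locus tag to the annotation of the reference provided, TAIR10.1, for 32489 genes. Its build name differs from that of the notes, so no positions are given. Product descriptions, transcript lengths and the symbols of genes outside the fixed lists came from it, and genes with neither a symbol nor a description are named by identifier. For each gene the share of 32-base words of its longest transcript found in the longest transcripts of other genes was computed. The share found in an organelle genome was computed too, and the rest of the nuclear genome was not searched. Genes sharing at least 50% were treated as unresolved copies (3045 genes, with 720 more lacking an exon model), a threshold chosen after the files were seen. Among the 3045 are 125 nuclear genes with at least that share in an organelle genome. Depth per library was recovered from transcripts of at least 2000 bp as the step between low FPKM values, from 0.6 to 4.5 steps. Between 75.3% and 92.1% of these values lay within 0.1 of a whole multiple. The depth so found was 4.11 to 49.2 M fragments. It erred by at most 3.20% in 3 simulated libraries of 5389 transcripts.

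Genes with at least 1 FPKM in at least 2 libraries were tested (22335 genes). Values were taken as log2(FPKM + 1), which shrinks differences of weakly expressed genes. A mean for each of the 10 groups was fitted with limma 3.58.1 in R 4.3.3, with a variance trend on expression and equal weights. All 20 libraries shared 1 estimate of spread, since a group has 2 libraries. In values given with an SE, n = 20 counts these libraries. A slope within a zone label rests on the libraries of that label, and a difference between 2 ages on the 2 libraries of each. Contrasts were the mean difference between zone labels over the 5 ages, any difference among ages and the linear trend per day within each zone label, days 5 against 3 and 7 against 5 within each, and any change and the trend of the zone difference with age. Adjusted p values are Benjamini-Hochberg values over all genes tested within a contrast, with a threshold of 0.05, from two-sided tests. A trend averaged over both zones was added after the data were seen. An exact 0 in the table was treated as listed at 0, not as absence.

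Lists of 321 genes in 21 groups were fixed, of which 300 genes were tested: mitosis and cytokinesis, DNA replication, ribosomes, stem cell niche, cell expansion, root hair, endodermal barriers, xylem, phloem, root cap, auxin, cytokinin, gibberellin and brassinosteroid, peroxidases and NADPH oxidases, wound and stress, phosphate, iron, nitrate, seed reserves, clock and photosynthetic tissue. They were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated, and with fry. Families were taken by words in product descriptions, whose patterns were adjusted after the descriptions were read, and tested apart from the lists; no description named Casparian strip membrane proteins. The contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined.

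By that rule the text names, for the zones, the 8 largest differences in each direction among called genes with a mean of at least 10 FPKM in the higher zone and no overlap between labels. For age trends it names up to 6 in each direction with a group mean of at least 10 FPKM, for the change of the zone difference up to 4 and for pairs of ages up to 3. Where none passed, the 3 with the smallest p are named as not passing. Each list gives up to 3 called members with the smallest p, and 12 genes were named in any case. One of the genes picked by this rule is not reported here. Unresolved copies and organelle genes were left out of ranked picks. The genes named for the trend over both zones and for any difference among ages, BRN1, AT3G50764, and the genes named for any change of the zone difference were chosen after their values were seen.

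Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, quantile normalisation, median-of-ratios scaling, limma's library weights (statmod 1.5.0 was installed), a robust variance prior, the replicate number as a term, and leaving out each library in turn. A group left with 1 library was assumed to vary like the others. Added after the data were seen were fits without the 4 libraries of replicate 2 at days 6 and 7, without the 2 of day 4, without the 3 of lowest estimated depth, with each library's trend on transcript length removed, and with transcripts of at least 300 bp. Removing the length trend also took out each library's overall shift. For the chance of each count, 100 splits of the libraries were drawn, the real one included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

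The fits were tested on simulated data in which 100 genes of each size were changed. The changed genes had a mean above 2 on the log2(FPKM + 1) scale, and values were drawn independently for each gene and library. The rates below therefore cover neither weaker genes nor deviations that many genes of a library share. For the zones 73% of genes with a change of 1 log2 and 96% with 2 log2 were called, and 3.98% of calls were false. For trends of 0.25 and 0.5 log2 per day, 11% and 61% were called in the libraries labelled MZ (6.49% of calls false) and 8% and 51% in those labelled EZ (6.35% false). For trends of the zone difference they were 0% and 9%. For any difference among ages 1% and 30% were called in the libraries labelled MZ and 1% and 31% in those labelled EZ, where 3.12% and 15.8% of calls were false. Any change of the zone difference gave 0% and 1%. Changes of 1 and 2 log2 between ages were called for 5% and 34% (days 7 and 5, MZ), 4% and 39% (days 5 and 3, MZ), 2% and 35% (days 7 and 5, EZ) and 4% and 40% (days 5 and 3, EZ), and 13.3%, 14.0%, 2.63% and 2.22% of calls were false. The set test called 1 list, the one that had been shifted. Its genes were simulated independently, so it does not show how the test fares with correlated genes. Removing a simulated length trend left 114 changed genes called and lowered other calls from 38 to 4.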

Results

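Transcript levels were measured by RNA sequencing in root cells of Arabidopsis thaliana Col-0 seedlings carrying PET111:GFP, a reporter of the columella, at 3, 4, 5, 6 and 7 days of age. Root sections labelled meristematic zone (MZ) or elongation zone (EZ) were digested to protoplasts, and cells without GFP were collected by sorting. Each zone at each age has 2 biological replicates, which gives 10 groups and 20 libraries. The deposited table lists FPKM for 33201 genes. It holds no read counts, and the depth recovered from the spacing of low FPKM values ran from 4.11 to 24.1 M fragments in the libraries labelled MZ and from 12.8 to 49.2 M in those labelled EZ. Between 15912 and 19251 genes reached 1 FPKM in a library. The correlation across genes between the 2 replicates of a group ran from 0.888 to 0.949, with a mean of 0.923, against 0.919 for libraries of the same zone at other ages and 0.890 for libraries of the other zone. At days 6 and 7 the replicates of both zones agreed less with each other than with libraries of the same zone at other ages (0.888 against 0.901 for EZ day 6). The best match was the own replicate for 2 of the 20 libraries and a library of the same zone for 19, and that of EZ day 7 replicate 2 was MZ day 6 replicate 2.

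The first comparison asked which transcripts differ between the zone where cells divide and the zone where they elongate. Genes of dividing cells were higher in the libraries labelled EZ, the opposite side from the zone names, so libraries are named by their labels throughout. PCNA1 (AT1G07370), the sliding clamp of DNA replication, averaged 39.2 ± 15.8 FPKM (SD, n = 10) in the libraries labelled EZ and 9.42 ± 5.27 FPKM (SD, n = 10) in those labelled MZ. The ribosomal protein gene RPS6A (AT4G31700) averaged 946 ± 267 FPKM (SD, n = 10) against 306 ± 107 FPKM (SD, n = 10). RCPG (AT1G65570), a root cap polygalacturonase, lay on the other side, at 158 ± 106 FPKM (SD, n = 10) in the libraries labelled EZ and 501 ± 243 FPKM (SD, n = 10) in those labelled MZ. By limma, 6334 of 22335 genes passed an adjusted p of 0.05 in the mean difference over the 5 ages, 4599 higher and 1735 lower in the libraries labelled EZ, and 8913 passed an unadjusted p of 0.05. The 10 libraries of each label did not overlap for 207 higher and 31 lower genes, where chance gives 0.00108% of genes in both directions together. The balance of directions depended on the scaling between libraries: the median difference of all tested genes was 0.15 on the log2(FPKM + 1) scale as deposited, -0.06 after quantile normalisation and 0.06 after median-of-ratios scaling, and the share of calls that were higher was 72.6%, 49.9% and 58.4%.

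All log2 values below are on the log2(FPKM + 1) scale, libraries labelled EZ minus MZ for the zones. Of 20 tested DNA replication genes, 17 were higher in the libraries labelled EZ and 0 lower over all genes (19 adjusted over the list alone), with a median of 1.29, or 1.13 above the median of all genes. PCNA1 differed by 2.02 ± 0.22 (SE, n = 20), and the helicase subunits MCM3 (AT5G46280) and MCM2 (AT1G44900) by 1.82 ± 0.21 and 1.63 ± 0.21. Of 18 genes of ribosome biogenesis and ribosomal proteins, 17 were higher (17 adjusted over the list alone), with a median of 1.61, or 1.46 above all genes. RPS6A differed by 1.64 ± 0.16, RPL5A (AT3G25520) by 1.45 ± 0.19 and EBP1 (AT3G51800), a regulator of organ growth, by 1.85 ± 0.24. Of 25 genes of mitosis and cytokinesis, 12 were higher (14 adjusted over the list alone), with a median of 1.00, or 0.85 above all genes. They included the cell cycle kinase CDKB2;2 (AT1G20930) at 1.66 ± 0.27, the anaphase activator CDC20.1 (AT4G33270) at 1.85 ± 0.39 and the mitotic kinase AUR1 (AT4G32830) at 1.14 ± 0.25. Of 19 stem cell niche and meristem regulators, 8 were higher (11 adjusted over the list alone), with a median of 0.78, or 0.63 above all genes. They included PLT1 (AT3G20840) at 2.25 ± 0.39 and PLT3 (AT5G10510) at 0.89 ± 0.21, transcription factors that maintain the root meristem, and the peptide RGF3 (AT2G04025) at 2.25 ± 0.31. In the limma set test camera with its preset correlation, adjusted p was 3.96e-08 for replication, 4.33e-10 for ribosomes, 0.00268 for mitosis and 0.0186 for the stem cell list. None of the 4 passed with an estimated correlation, where adjusted p was 0.401, 0.401, 0.445 and 0.405. As deposited, the mean of each of these lists over the 2 replicates was higher in the libraries labelled EZ at 5 of 5 ages. For mitosis the difference at day 7 was 0.07, less than the gap between the medians of all tested genes there. Those medians were 3.17 and 2.88 in the libraries labelled EZ and 2.68 and 2.39 in those labelled MZ. Over the 5 ages the list medians kept this direction, higher in the libraries labelled EZ, under both other scalings. Single libraries departed from it: in EZ day 6 replicate 2 the mean was 1.62 for mitosis and 6.39 for ribosomes, against 2.55 and 6.78 in MZ day 6 replicate 2, and in EZ day 7 replicate 1 it was 2.26 for mitosis, against 2.28 in MZ day 7 replicate 1.

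**Figure D1:**
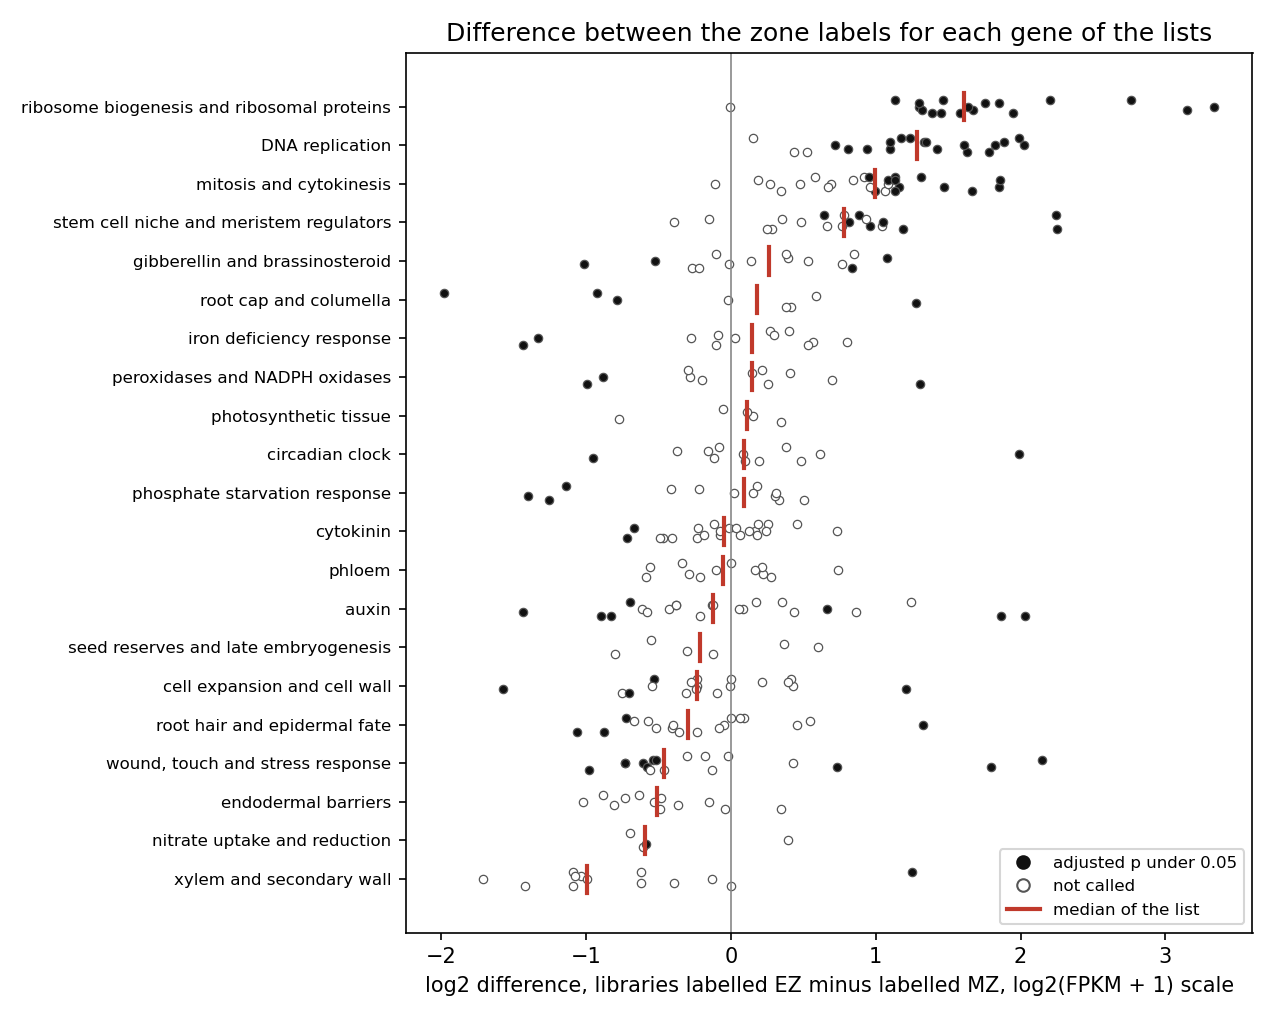
Difference between the libraries labelled EZ and those labelled MZ on the log2(FPKM + 1) scale for the tested genes of the fixed lists. The DNA replication genes centre at 1.29, while the endodermal barrier genes centre at -0.51, against a median of 0.15 for all tested genes; the medians of the root cap, clock, iron, phosphate, photosynthetic and peroxidase lists turn negative after quantile normalisation.

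Lists of differentiating cells had lower medians in the libraries labelled EZ over the 5 ages, again the opposite side from the zone names, although few members were called. Where the counts of a fixed list adjusted over the list alone are not given, here and below, they equal those over all genes. In the cell expansion and cell wall list of 18 genes, 1 was higher and 3 were lower, with a median of -0.23. The lower ones included the cellulose synthase CESA1 (AT4G32410), at -0.71 ± 0.14 (SE, n = 20), and EXPA17 (AT4G01630), an expansin that loosens cell walls, at -1.57 ± 0.49. The xyloglucan enzyme gene XTH20 (AT5G48070) was higher, by 1.21 ± 0.32. In the root hair and epidermal fate list of 18, 1 was higher and 3 were lower, with a median of -0.30. EXPA7 (AT1G12560), an expansin of root hair cells, differed by -1.06 ± 0.28, the cell wall gene LRX2 (AT1G62440) by -0.88 ± 0.21 and the epidermal fate factor EGL3 (AT1G63650) by 1.32 ± 0.30. The endodermal barrier list of 12 had 0 calls by limma, 0 adjusted over the list alone, and a median of -0.51; its mean was 1.27 in EZ day 6 replicate 2 and 4.25 to 6.52 in the other libraries. In the xylem and secondary wall list of 13, with a median of -0.996, only ACL5 (AT5G19530), a thermospermine synthase, was called, and it was higher, by 1.25 ± 0.41 (0 adjusted over the list alone). The mean of that list varied widely between libraries. It was 0.704 and 3.864 in the replicates of EZ day 5, and 5.458 and 1.089 in those of MZ day 7. The means of the cell expansion, root hair and xylem lists were lower in the libraries labelled EZ at days 3 to 6 and higher at day 7, by 0.04, 0.09 and 0.08. That of the endodermal list was lower at days 3, 4 and 6, by 2.52 at day 6, and higher at days 5 and 7, by 0.39 and 0.80. These means were taken as deposited. At day 7 the medians of all tested genes were also higher in the libraries labelled EZ, at 3.17 and 2.88 against 2.68 and 2.39. At day 5 they were 3.11 and 3.26 against 2.65 and 2.96. Adjusted p by camera was 0.0343, 0.0237, 0.0237 and 0.0338 for these 4 lists, and 0.445, 0.445, 0.514 and 0.566 with an estimated correlation. The call of ACL5 ended in 11 of the 20 fits that left out 1 library, and that of EXPA17 in 6 of them: MZ day 4 replicate 1, MZ day 5 replicate 2, MZ day 6 replicate 1, MZ day 7 replicate 1, EZ day 3 replicate 1 and EZ day 6 replicate 2.

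Genes of stress handling were divided between the labels. In the wound, touch and stress list of 17 genes, 3 were higher and 7 were lower in the libraries labelled EZ, with a median of -0.46 (camera adjusted p 0.0186, and adjusted p = 0.401 with an estimated correlation). The chaperones HSP101 (AT1G74310) and HSP70 (AT3G12580) were higher, by 2.15 ± 0.32 and 1.79 ± 0.24 (SE, n = 20). JAZ1 (AT1G19180), a repressor of jasmonate signalling, was lower, at 495 ± 103 FPKM (SD, n = 10) against 814 ± 106 FPKM (SD, n = 10). Among 37 genes described as heat shock proteins, 22 were higher and 1 lower (25 and 3 adjusted over the family alone), with a median of 1.22. The called gene with the largest difference and no overlap between labels, AT1G53540, encodes a small heat shock protein and read between 4.26 and 71.6 FPKM in the libraries labelled EZ and at most 2.29 FPKM in those labelled MZ, where 1 library listed it at 0.

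Other gene groups had members on both sides. In the auxin list of 22 genes, 3 were higher and 5 lower (4 and 6 adjusted over the list alone), and its median of -0.13 and mean of 0.05 differed in sign (camera adjusted p 0.0673). The influx carrier LAX2 (AT2G21050) was higher, by 1.86 ± 0.39 (SE, n = 20), and the auxin response repressor IAA14 (AT4G14550) was at -1.43 ± 0.18. Of 22 cytokinin genes 2 were lower, the receptor AHK4 (AT2G01830) and the response regulator ARR3 (AT1G59940), at -0.72 ± 0.21 and -0.67 ± 0.18, and the median of that list was -0.05 (camera adjusted p 0.0673). The gibberellin and brassinosteroid list of 14 had 2 higher and 2 lower genes (4 and 2 adjusted over the list alone), among them the brassinosteroid enzymes BR6OX2 (AT3G30180), for synthesis, at 1.08 ± 0.28 and BAS1 (AT2G26710), for inactivation, at -1.02 ± 0.20, and the gibberellin-regulated GASA4 (AT5G15230) at -0.52 ± 0.15. Its median of 0.26 was positive while camera gave the downward direction (adjusted p 0.896). Of 8 root cap genes, RCPG, BRN1 (AT1G33280) and BRN2 (AT4G10350), the latter 2 regulators of cap cell maturation, were lower and FEZ (AT1G26870), a regulator of cap stem cell divisions, was higher. RCPG differed by -1.98 ± 0.28, BRN2 by -0.93 ± 0.28 and FEZ by 1.28 ± 0.28. The median of the root cap list was 0.18 and its mean -0.13 (camera adjusted p 0.304), and the median was negative after quantile normalisation and with the length trend removed. BRN2 lost its call without MZ day 4 replicate 2, MZ day 7 replicate 2 or EZ day 7 replicate 1 (highest adjusted p 0.0526), and BRN1 without MZ day 5 replicate 1, MZ day 7 replicate 2 or EZ day 6 replicate 1 (0.0530).

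In the nutrient lists the called genes were lower in the libraries labelled EZ. They were 3 of 12 phosphate starvation genes, 2 of 12 iron deficiency genes and 1 of 4 nitrate genes. FRO2 (AT1G01580), the root ferric reductase, and its regulator FIT (AT2G28160) were at -1.44 ± 0.24 and -1.33 ± 0.20 (SE, n = 20). The phosphate transporter PHT1;4 (AT2G38940), the lipid synthases SQD2 (AT5G01220) and MGD3 (AT2G11810), and the nitrite reductase NIR1 (AT2G15620) were at -1.25 ± 0.27, -1.14 ± 0.24, -1.40 ± 0.45 and -0.58 ± 0.15. MGD3 lost its call in 11 of the 20 fits that left out 1 library. Camera adjusted p was 0.115, 0.304 and 0.0682 for the 3 lists. The medians of the phosphate and iron lists were 0.09 and 0.15 and their means -0.22 and -0.03, and both medians were negative after quantile normalisation and with the length trend removed. The nitrate median was -0.60.

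Of 11 peroxidase and NADPH oxidase genes 1 was higher and 2 were lower: PER40 (AT4G16270) at 1.30 ± 0.29, PER57 (AT5G17820) at -0.88 ± 0.23 and the oxidase RBOHF (AT1G64060) at -0.99 ± 0.30 (SE, n = 20), whose call ended without MZ day 3 replicate 1, MZ day 6 replicate 1, EZ day 5 replicate 1 or EZ day 7 replicate 2 (highest adjusted p 0.0546). Their median was 0.14, which turned negative after quantile normalisation and with the length trend removed, and camera gave the downward direction (adjusted p 0.383). Of 12 clock genes GRP7 (AT2G21660), a clock-regulated RNA-binding protein, was higher, by 1.99 ± 0.32, and ELF4 (AT2G40080), an evening clock component, was lower, at -0.95 ± 0.17. The clock median of 0.09 (camera downward, adjusted p 0.725) was negative under both other scalings and with the length trend removed. By limma 0 genes were called in the phloem, seed reserve and photosynthetic lists of 12, 6 and 5 tested genes, with medians of -0.05, -0.21 and 0.11 and camera adjusted p of 0.264, 0.383 and 0.584; the photosynthetic mean was -0.04, and its median turned negative after quantile normalisation and with the length trend removed.

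**Figure D2:**
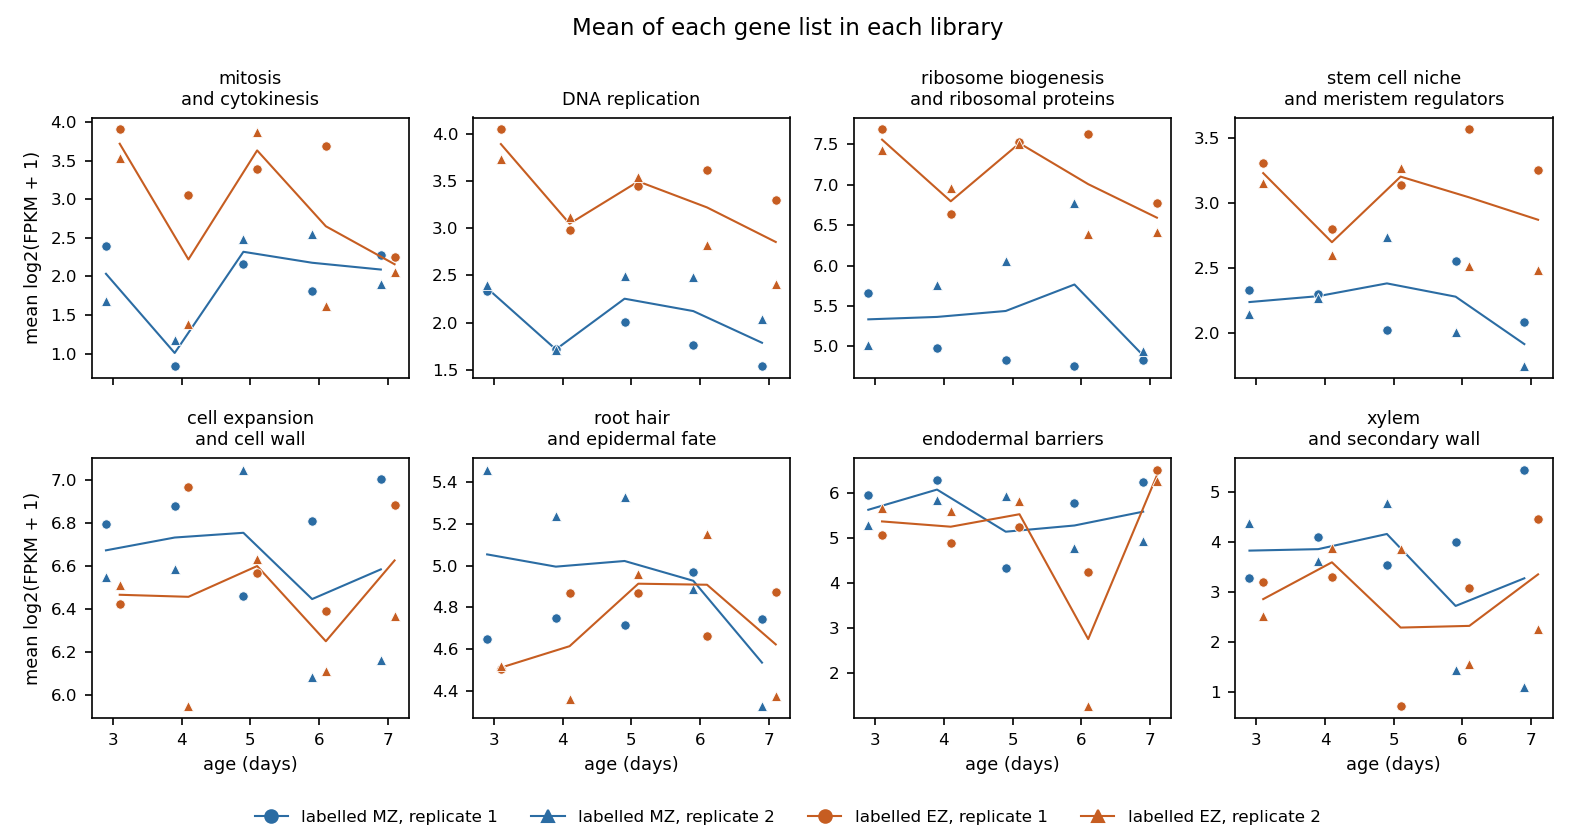
Mean log2(FPKM + 1) of the tested genes of fixed lists in each of the 20 libraries, by age in days and zone label. The means of the DNA replication list differ by 1.52 at day 3 and 1.07 at day 7 between labels, and those of the mitosis list by 1.69 and 0.07, higher in the libraries labelled EZ.

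Families taken from product descriptions gave a like picture for growth genes. Of 293 cytosolic ribosomal protein genes, 243 were higher and 5 lower in the libraries labelled EZ, with a median of 1.26. Of 43 histone genes 24 were higher and 1 lower (median 0.86), of 58 cyclins 23 and 1 (median 0.50) and of 27 kinesins 7 and 1 (median 0.33). Camera adjusted p was 2.64e-34, 6.11e-05, 0.00210 and 0.230 for these 4 families, and 8.36e-07 for heat shock proteins. With an estimated correlation the smallest adjusted p of any family was 0.277. Aquaporins had 1 higher and 8 lower genes of 29 (camera adjusted p 0.000360), glutathione S-transferases 4 and 9 of 50 (0.00445), peroxidases 4 and 9 of 56 (0.00616), extensins 10 and 15 of 107 (0.00616) and arabinogalactan proteins 5 and 8 of 54 (0.00776). WRKY factors had 1 higher and 6 lower genes of 60 (0.0123), cytochromes P450 13 and 18 of 154 (0.0329), pectin methylesterases 6 and 9 of 69 (0.0354), expansins 4 and 5 of 23 (0.122) and xyloglucan endotransglucosylases 3 and 5 of 25 (0.122). The median of the P450 and xyloglucan families was positive as deposited, and negative after either other scaling. Laccases had 1 higher and 1 lower gene of 13, SAUR proteins 7 and 4 of 51 and defensins 5 and 1 of 50, and germins had 0 limma calls of 12; the SAUR median turned negative after quantile normalisation and with the length trend removed. Adjusted over the family alone, the higher and lower counts were 252 and 7 for ribosomal proteins, 24 and 3 for histones, 26 and 1 for cyclins, 5 and 6 for expansins, 10 and 11 for extensins and 4 and 7 for arabinogalactan proteins. They were 1 and 3 for WRKY factors, 13 and 16 for P450s, 1 and 0 for laccases, 7 and 3 for SAUR proteins and 3 and 1 for defensins, and unchanged for kinesins, aquaporins, glutathione S-transferases, peroxidases, pectin methylesterases, xyloglucan endotransglucosylases and germins.

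The other genes with the largest differences and no overlap between labels served various functions. On the higher side, the prefoldin chaperone gene AT5G27330 differed by 2.41 ± 0.32, the replication factor RPA70D (AT5G61000) by 2.41 ± 0.33, the translation protein AT5G67510 by 2.39 ± 0.31 and the rRNA processing protein AT5G61330 by 2.35 ± 0.28 (SE, n = 20). The arginine methyltransferase PRMT1A (AT2G19670) differed by 2.34 ± 0.34 and the histone HTB2 (AT5G22880) by 2.26 ± 0.27. On the lower side the largest difference was that of the aspartyl protease AT4G04460, at 47.6 ± 24.0 FPKM (SD, n = 10) in the libraries labelled EZ and 238 ± 86.2 FPKM (SD, n = 10) in those labelled MZ. The fatty acid hydroxylase AT2G37700, the Bax inhibitor family gene AT1G03070, the berberine bridge family gene MEE23 (AT2G34790) and the papain family protease AT4G16190 were between -2.00 and -1.82. AT5G20700, the calmodulin CAM8 (AT4G14640) and AT1G77770 were at -1.27 ± 0.13, -1.18 ± 0.17 and -1.16 ± 0.13. All of these genes were called in each of the 20 fits that left out 1 library.

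Genes to be named whatever their values included further regulators. PLT2 (AT1G51190), SHR (AT4G37650) and SCR (AT3G54220), transcription factors of the stem cell niche and ground tissue, were higher in the libraries labelled EZ, by 0.82 ± 0.25, 1.19 ± 0.39 and 1.05 ± 0.32 (SE, n = 20; limma adjusted p 0.0232, 0.0361 and 0.0229). SHR lost its call in 12 of the 20 fits that left out 1 library. PLT2 lost it without MZ day 4 replicate 1, MZ day 5 replicate 1, EZ day 3 replicate 1 or EZ day 6 replicate 1, and SCR without MZ day 5 replicate 1, MZ day 7 replicate 2 or EZ day 3 replicate 1, with highest adjusted p of 0.0559 and 0.0544. CYCB1;1 (AT4G37490), a mitotic cyclin, differed by 1.07 ± 0.41 and missed the threshold (adjusted p 0.0669), which it passed without EZ day 4 replicate 2 (0.0286) or EZ day 6 replicate 2 (0.00608). CASP1 (AT2G36100), a protein of the Casparian strip, was at -0.49 ± 0.49 (adjusted p 0.490, and 0.0364 without EZ day 6 replicate 1), and UPB1 (AT2G47270), a repressor of peroxidase genes, at -0.39 ± 0.20 (adjusted p 0.153, and 0.0274 without EZ day 4 replicate 1). The cytokinin response factors ARR1 (AT3G16857) and ARR12 (AT2G25180) were at -0.23 ± 0.12 and -0.18 ± 0.13, with adjusted p of 0.156 and 0.332. ARR1 passed after median-of-ratios scaling (0.0279) and, like UPB1 (0.0362), with the length trend removed (0.0114). CYCB1;1 passed with limma's library weights (0.0457) and without the 4 libraries of replicate 2 at days 6 and 7 (0.00956). The auxin repressor SHY2 (AT1G04240) was at 0.17 ± 0.26 (adjusted p 0.650), a direction that turned after quantile normalisation. WOX5 (AT3G11260), a marker of the quiescent centre, was listed at 0 in 7 libraries and read at most 5.59 FPKM in those labelled MZ and 30.2 FPKM in those labelled EZ, with an adjusted p of 0.492. Without the 3 libraries of lowest depth, a setting chosen after the data were seen, 4177 genes were called, and EXPA17, ACL5, ARR3, AHK4, RBOHF, MGD3, GASA4, PLT2 and SHR lost their calls. ACL5, PLT2, SHR and SCR lost theirs after quantile normalisation, and XTH20, EXPA7, ARR3, BRN2, GASA4, RBOHF, ACL5, SHR and SCR without the 2 day 4 libraries of replicate 2. EXPA17, ACL5, BRN2, RBOHF, MGD3 and SHR lost theirs with no filter (highest adjusted p 0.0734), EXPA17 and NIR1 without the 4 libraries of replicate 2 at days 6 and 7 (0.0617 for both), and ACL5 and PLT2 with the length trend removed (0.0506 and 0.0612).

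The next comparison asked how transcript levels changed as the root grew from 3 to 7 days. Here and below, n = 20 counts the libraries that gave the estimate of spread. A slope within a zone label rests on the libraries of that label only, and a difference between 2 ages on the 2 libraries of each. In the libraries labelled MZ, AGL17 (AT2G22630), a MADS-box transcription factor, read 8.84 and 5.95 FPKM at day 3 and 24.9 and 28.8 FPKM at day 7 in the 2 replicates, a slope of 0.49 ± 0.07 log2 per day (SE, n = 20). WES1 (AT4G27260), a GH3 enzyme that conjugates auxin, rose by 0.41 ± 0.07 per day, from a mean of 20.4 FPKM to 54.6 and 75.5 FPKM. KIN1 (AT5G15960), a cold and abscisic acid response gene, had a slope of -0.78 ± 0.13, from 29.7 to 3.28 FPKM, and ELF4 one of -0.43 ± 0.09, from 154 to 48.9 FPKM. OPT3 (AT4G16370), a phloem transporter of the iron deficiency list, had a slope of -0.53 ± 0.11, from 30.8 to 6.13 FPKM. By limma 205 genes had an age trend at an adjusted p of 0.05, 15 rising and 190 falling, and 2897 passed an unadjusted p of 0.05. The median slope of all tested genes was -0.05 as deposited, and the count was 49, with 26.5% rising, after quantile normalisation and 48, with 27.1% rising, after median-of-ratios scaling, where 7.32% rose as deposited. The 190 falling genes kept a median slope of -0.29 after either scaling, against -0.34 as deposited. With the transcript length trend removed, 12 genes were called, and KIN1, WES1, ELF4 and OPT3 lost their calls, as all 5 named genes did without the 3 libraries of lowest depth or the 4 libraries of replicate 2 at days 6 and 7. ELF4 and OPT3 also lost theirs after either other scaling, WES1, ELF4 and OPT3 without the 2 day 4 libraries of replicate 2, and OPT3 with a pseudocount of 0.1 (adjusted p 0.0503) or no filter (0.0529). The count was 11 without MZ day 3 replicate 1, 11 without MZ day 3 replicate 2, 135 without MZ day 4 replicate 1, 64 without MZ day 4 replicate 2, 7 without MZ day 7 replicate 2, 114 without EZ day 3 replicate 1 and 117 without EZ day 3 replicate 2. AGL17 lost its call without MZ day 3 replicate 2 (adjusted p 0.0823) or MZ day 7 replicate 2 (0.0651). KIN1 lost its call without either MZ day 3 library or MZ day 7 replicate 2, WES1 without these or MZ day 4 replicate 2, and ELF4 and OPT3 in 7 and 16 of the 20 fits that left out 1 library.

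Further rising genes in the libraries labelled MZ were AT1G50050, of the cysteine-rich secretory proteins, at 0.81 ± 0.13 per day (SE, n = 20), and AT5G43520, with a C1 domain, at 0.74 ± 0.12. Both lost their calls without either MZ day 3 library or MZ day 7 replicate 2, with a highest adjusted p of 0.104 for the former. AT3G54804 and AT2G13363 were listed at 0 in 18 and 17 libraries, and AT2G13363 lost its call in 10 of the 20 fits that left out 1 library. AT3G54804 read 28.9 and 22.4 FPKM in the libraries labelled MZ of day 7. Further falling genes were the late embryogenesis gene AT2G33690 at -0.77 ± 0.16, the stress tolerance gene AT4G33660 at -0.68 ± 0.13, the hydrolase AT4G16820 at -0.67 ± 0.12 and AT5G35740, with a carbohydrate-binding domain, at -0.64 ± 0.13. Their calls ended in 11, 5, 5 and 13 of the 20 fits that left out 1 library, and all 4 ended with the length trend removed. AT2G22426, of unknown function, was listed at 0 in 15 libraries and fell by 0.93 ± 0.17 per day, a call lost without MZ day 3 replicate 1, MZ day 7 replicate 1 or MZ day 7 replicate 2, with a pseudocount of 5 and with the length trend removed. Of these further genes only AT3G54804 kept its call without the 3 libraries of lowest depth or the 4 libraries of replicate 2 at days 6 and 7, and only AT3G54804 and AT5G43520 without the 2 day 4 libraries of replicate 2. AT2G33690, AT4G33660 and AT5G35740 lost theirs after either other scaling, AT4G16820 after quantile normalisation, and AT5G35740 with no filter. AT2G13363, AT2G33690, AT4G33660 and AT4G16820 lost theirs with a pseudocount of 0.1, and AT2G13363 also with a filter at 5 FPKM or limma's library weights. Mitosis and cytokinesis genes had a median slope of 0.15 per day, with 0 of 25 called by limma (camera upward, adjusted p 0.00654, and adjusted p = 0.997 with an estimated correlation). Ribosomal protein and histone families each had 0 rising and 2 falling genes, and 4 and 14 fell when adjusted over the list alone (camera adjusted p 1.10e-08 for both, and adjusted p = 0.880 and 0.686 with an estimated correlation).

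Any difference among the 5 ages, tested together, was called for 92 genes in the libraries labelled MZ, with 2116 at an unadjusted p of 0.05. The genes named here were chosen after their values were seen. ACBP6 (AT1G31812), an acyl-CoA-binding protein, had group means between 318 and 434 FPKM from day 3 to day 6 and read 82.4 and 80.0 FPKM at day 7 (limma adjusted p 0.00300). SPR1 (AT2G03680), a microtubule-associated protein of directional cell growth, had means between 316 and 360 FPKM and then 106 FPKM (adjusted p 0.0170), and the transcriptional coactivator MBF1A (AT2G42680) between 174 and 246 FPKM and then 69.4 FPKM (0.0148). All 3 lost their calls without either MZ day 7 library, with highest adjusted p of 0.0689, 0.190 and 0.135. The count was 23 and 31 without MZ day 3 replicate 1 or 2, 59 and 55 without MZ day 4 replicate 1 or 2, 60 without MZ day 5 replicate 2, and 2 and 12 without MZ day 7 replicate 1 or 2. It was 28 without either EZ day 3 library, 52 without either EZ day 4 library and 43 without either EZ day 5 library. After quantile normalisation it was 41, after median-of-ratios scaling 38 and with the length trend removed 6.

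Between days 5 and 7 in the libraries labelled MZ, 68 genes changed by limma, 12 upward and 56 downward (2391 at an unadjusted p of 0.05). Of the 12, 6 are encoded in an organelle genome and 9 lack an exon model in the annotation, and organelle genes held 1.22% and 1.47% of the FPKM in the 2 libraries of day 5 and 2.38% and 2.97% in those of day 7. This balance depended on the scaling: 11 went upward and 12 downward after quantile normalisation, and 15 and 8 after median-of-ratios scaling. It was 26 and 26 without the 4 libraries of replicate 2 at days 6 and 7. KDR (AT1G26945), a basic helix-loop-helix regulator of light responses, had a log2 difference of -3.08 ± 0.50 (SE, n = 20), from a mean of 11.6 to 0.426 FPKM. OEP7 (AT3G52420), an outer envelope protein of plastids, was at -2.37 ± 0.34, and the ribosomal protein L39 gene AT4G31985 at -2.25 ± 0.41. AT1G25400, of unknown function, rose by 1.49 ± 0.26, from 120 to 337 FPKM. AT3G54804 and AT2G13363 were listed at 0 in both libraries labelled MZ of day 5, and AT2G13363 averaged 10.1 FPKM at day 7. AT2G13363, AT1G25400, KDR and AT4G31985 lost their calls in 12, 12, 6 and 11 of the 20 fits that left out 1 library, and OEP7 without MZ day 5 replicate 2, MZ day 7 replicate 1 or MZ day 7 replicate 2. The count was 21 without either MZ day 3 library, 23 without either MZ day 4 library, 41 and 3 without MZ day 5 replicate 1 or 2, and 9 and 23 without MZ day 7 replicate 1 or 2. It was 14 without either EZ day 3 library, 45 without either EZ day 4 library and 20 without either EZ day 5 library, and 4, all downward, with the length trend removed, where KDR, AT1G25400 and AT4G31985 were not called. Of the named genes only AT3G54804 kept its call without the 3 libraries of lowest depth, AT3G54804 and AT4G31985 without the 4 libraries of replicate 2 at days 6 and 7, and AT3G54804 and OEP7 without the 2 day 4 libraries of replicate 2. AT4G31985 lost its call after either other scaling, KDR with a pseudocount of 5 (adjusted p 0.0748) and AT2G13363 with a pseudocount of 0.1, a filter at 5 FPKM or library weights.

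Between days 3 and 5 in the libraries labelled MZ, 0 genes passed limma's adjusted p of 0.05, with 700 at an unadjusted p of 0.05. The genes with the smallest p were higher at day 5 for AT5G43520, at 2.32 ± 0.54 log2 (SE, n = 20; adjusted p 0.408), the kinase AT5G11850 (0.417) and KIN10 (AT3G01090), a SnRK1 kinase of energy signalling (0.528). They were lower for AT4G06477 at -2.91 ± 0.52 (adjusted p 0.133), OPT3 at -2.50 ± 0.51 (0.235) and the lipid transfer protein AT5G01870 (0.230), which was listed at 0 in both libraries of day 5. The count was 7 without MZ day 3 replicate 2, 2 without MZ day 5 replicate 2, 1 without either EZ day 3 library and 12 without either EZ day 7 library. With limma's library weights it was 14, and AT4G06477 then passed (adjusted p 0.0332), as KIN10 did with no filter (0.0272).

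In the libraries labelled EZ, AGL17 rose by 0.68 ± 0.07 log2 per day (SE, n = 20), from 3.13 and 2.65 FPKM at day 3 to 20.5 and 28.1 FPKM at day 7. GA20OX5 (AT1G44090), of the gibberellin 20-oxidases, had a slope of -1.21 ± 0.17, from 24.8 and 36.1 FPKM to 1.45 FPKM and 0. AT3G01572, of unknown function, read 18.5 and 16.4 FPKM at day 7 and was listed at 0 in the other 18 libraries. These 3 genes were the ones called by limma, with 1860 at an unadjusted p of 0.05. GA20OX5 lost its call in 12 of the 20 fits that left out 1 library, AGL17 without the 4 libraries of replicate 2 at days 6 and 7 (adjusted p 0.153), and AT3G01572 with a filter at 5 FPKM (0.0615). GA20OX5 also lost its call with that filter (0.0509), a pseudocount of 0.1 or library weights, and without the 3 libraries of lowest depth, the 4 of replicate 2 at days 6 and 7 or the 2 of day 4. The count was 8 without either MZ day 4 library, 5 without either EZ day 5 library, 12 without EZ day 6 replicate 1 and 31 without EZ day 7 replicate 1. Of the 205 genes with a trend in the libraries labelled MZ, 149 had a slope of the same sign here (72.7%, against 61.4% of all genes), and 1, AGL17, was called in both.

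Lists of dividing cells had falling medians in the libraries labelled EZ. The median slope was -0.29 per day for mitosis (camera adjusted p 3.71e-05), -0.21 for DNA replication (3.71e-05) and -0.16 for ribosomes (0.000519), with 0 members called by limma. With an estimated correlation adjusted p was 0.592, 0.509 and 0.826. The slopes were lower in the libraries labelled EZ than in those labelled MZ by camera for mitosis (adjusted p 1.84e-10), replication (0.00469) and ribosomes (0.0221), and adjusted p was 0.972 for all 3 with an estimated correlation. Without the 4 libraries of replicate 2 at days 6 and 7, the median slopes in the libraries labelled EZ were -0.11, -0.05 and -0.08, and the median differences in slope turned from -0.08 to 0.09 for replication and from -0.08 to 0.11 for ribosomes, while that of mitosis went from -0.32 to -0.29. The mean of the mitosis list was higher in the libraries labelled EZ by 1.69 at day 3, 1.21 at day 4, 1.31 at day 5, 0.47 at day 6 and 0.07 at day 7.

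Any difference among the 5 ages was called for 12 genes in the libraries labelled EZ, with 1785 at an unadjusted p of 0.05. AGL17 was among them (adjusted p 0.00290, and 0.0685 without EZ day 3 replicate 2), and 10 of the 12 were listed at 0 in at least 10 libraries. The count was 35 without EZ day 6 replicate 1 and 22 without EZ day 7 replicate 1. Between days 3 and 5 there, limma called 2 genes, both higher, with 775 at an unadjusted p of 0.05. AT3G50764, named after its values were seen, was listed at 0 at day 3 and averaged 7.91 FPKM at day 5. AGL17 rose by 2.55 ± 0.32 log2 (SE, n = 20), a call lost without EZ day 3 replicate 1 (adjusted p 0.106), EZ day 3 replicate 2 (0.218), EZ day 5 replicate 1 (0.155) or EZ day 5 replicate 2 (0.108), without the 4 libraries of replicate 2 at days 6 and 7 (0.0917) or the 3 of lowest depth (0.0545), and with the length trend removed (0.0537). The lower genes with the smallest p did not pass: AT1G47395 (adjusted p 0.185), the microRNA gene MIR171c (AT1G62035, 0.185) and AT2G13126 (0.299). MIR171c passed without MZ day 4 replicate 1 (2.01e-05), MZ day 4 replicate 2 (1.08e-05) or the 2 day 4 libraries of replicate 2 (3.79e-05), and AT1G47395 and MIR171c with library weights (0.0380 and 0.0436). The count was 5 without either MZ day 4 library, 1 without EZ day 3 replicate 1 and 4 without either EZ day 4 library. Between days 5 and 7 limma called 2 genes, 1 higher and 1 lower, with 1366 at an unadjusted p of 0.05. AT3G01572 was the higher one, a call lost with a filter at 5 FPKM (adjusted p 0.0723). AT3G50764, named after its values were seen, was the lower one, listed at 0 at day 7. Among genes with a group mean of at least 10 FPKM, those with the smallest p that were lower at day 7 without passing were the proteasome subunit RPT4A (AT5G43010) at -1.02 ± 0.21 (adjusted p 0.672), the chaperone HSP23.6-MITO (AT4G25200) and the RNA-binding protein AtRZ-1c (AT5G04280), both with adjusted p of 0.755. RPT4A passed with no filter (0.0318). The count was 5 without EZ day 5 replicate 1 and 20 without EZ day 7 replicate 1.

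A trend averaged over both zones, a comparison chosen after the data were seen, was called for 54 genes, 21 rising and 33 falling. Here too the balance depended on the scaling, with 46 rising and 25 falling after quantile normalisation and 19 and 15 after median-of-ratios scaling. AGL17 rose by 0.58 ± 0.05 log2 per day (SE, n = 20; limma adjusted p 0.000215). The peroxidase gene AT2G39040 rose by 0.37 ± 0.05 (0.00965), from 175 and 180 FPKM at day 3 to 502 and 547 FPKM at day 7 in the libraries labelled MZ and from 103 and 98.6 to 199 and 322 FPKM in those labelled EZ. OPT3 had a slope of -0.61 ± 0.08 (0.00777), and the cyclophilin-type gene AT2G38730 one of -0.31 ± 0.04 (0.0168), where AT2G38730 lost its call in 5 of the 20 fits that left out 1 library and AT2G39040 without MZ day 7 replicate 2 or EZ day 3 replicate 2 (highest adjusted p 0.0510). Of the 54 genes, 23 were also called after quantile normalisation and with the length trend removed, 14 of them rising. The count was 267 without MZ day 7 replicate 1, 241 without EZ day 6 replicate 1 and 168 without EZ day 7 replicate 1. It was 10 and 14 without MZ day 3 replicate 1 or 2, 20 without MZ day 4 replicate 2, 33 and 32 without MZ day 5 replicate 1 or 2, 29 without MZ day 6 replicate 2 and 7 without MZ day 7 replicate 2. It was 10 and 9 without EZ day 3 replicate 1 or 2, 25 and 21 without EZ day 4 replicate 1 or 2, 19 without either EZ day 5 library, 21 without EZ day 6 replicate 2 and 9 without EZ day 7 replicate 2.

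**Figure D3:**
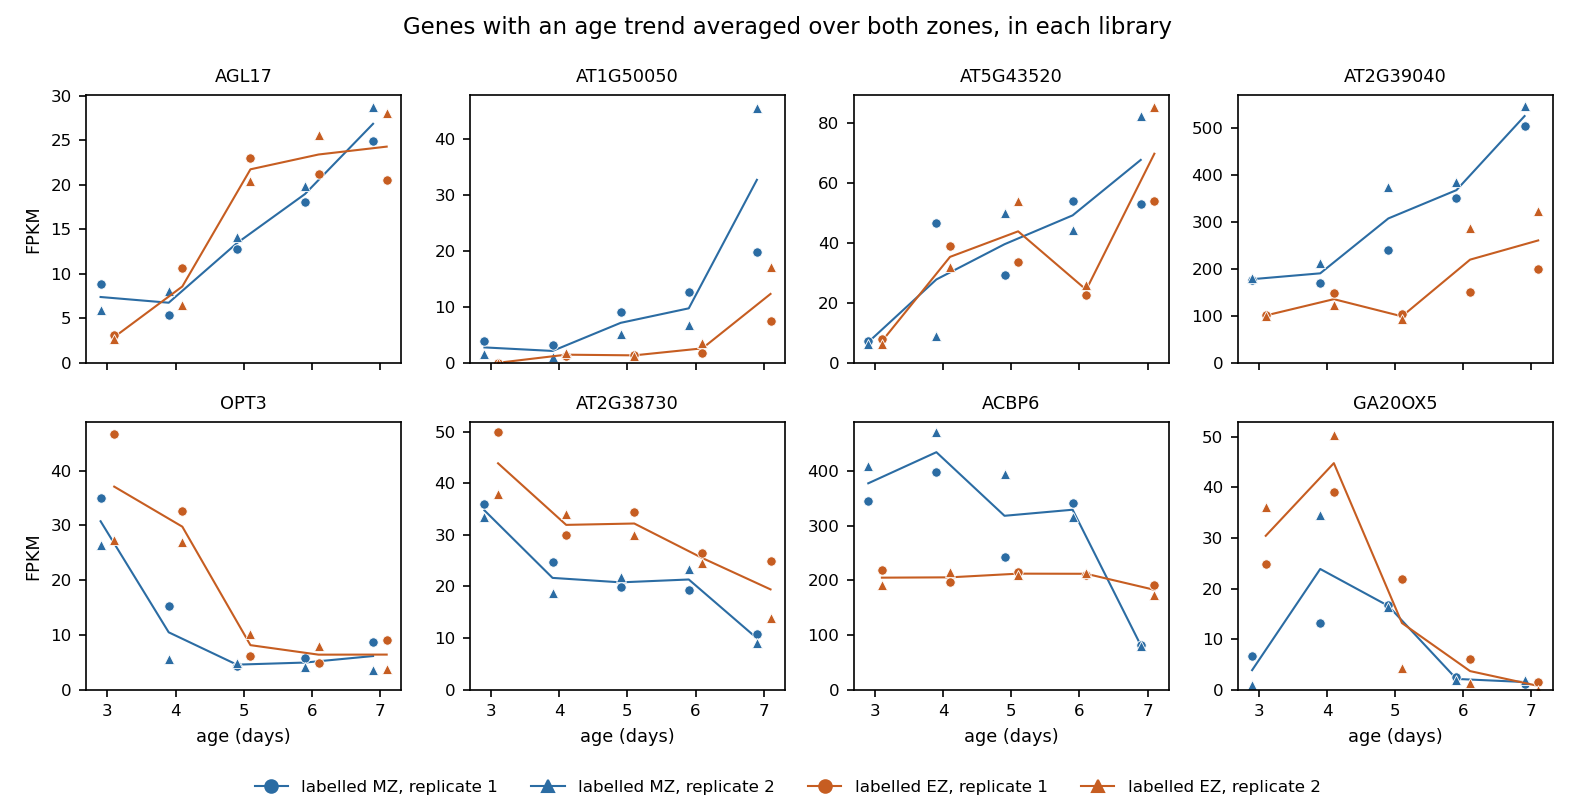
FPKM in each library against age in days for 4 genes with a rising and 4 with a falling trend averaged over both zones; the genes were chosen after the data were seen. AGL17 lies between 2.65 and 8.84 FPKM in the libraries of day 3 and between 20.5 and 28.8 FPKM in those of day 7.

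The last comparison asked whether the zone difference itself changed with age. By limma it differed among ages for 10 genes, with 1032 at an unadjusted p of 0.05, and had a trend for 2 genes, with 1364. AT3G54804 and AT3G01572 were these 2, each above 0 in the 2 libraries of a single group at day 7, labelled MZ for the former and EZ for the latter. AT4G06477, of unknown function, had the highest group mean of the 10, at 74.0 FPKM in the libraries labelled EZ of day 6, against 2.58 FPKM in those labelled MZ. The first count was 16 without MZ day 4 replicate 2, 4 without either MZ day 6 library and 22 without EZ day 7 replicate 1. The count of trends was 5 without MZ day 3 replicate 2, 4 without MZ day 4 replicate 1, 4 without either EZ day 5 library and 9 without EZ day 7 replicate 1. AT4G06477 lost its call in 12 of the 20 fits that left out 1 library. With a pseudocount of 0.1 limma called 0 genes in both tests (994 and 1359 at an unadjusted p of 0.05), and with a filter at 5 FPKM also 0 (669 and 1035). The trends of AT3G01572 and AT3G54804 were also not called with blocks of age and replicate number (adjusted p 0.170 and 0.144) or without the 3 libraries of lowest depth (0.0989 and 0.0886), and that of AT3G01572 not with the length trend removed (0.0683).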

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

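Of the tests in this part, the splits of the libraries for the zones and for the trend within the libraries labelled MZ, and the tests of a zone difference that changes with age, were planned; the tests of exchanged labels, scaling, transcript length, left-out libraries and values listed at 0 were chosen after the results were seen.

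Genes of dividing cells were higher in the libraries labelled EZ, by 0.95 ± 0.15 log2 relative to all genes (SE) over the 82 tested genes of the replication, ribosome, mitosis and stem cell lists, and in 9 of 10 pairs of libraries of equal age and replicate number. Transcript length is argued against as the whole cause, since the difference was 0.96 ± 0.15 with the length trend removed. After quantile normalisation it was 0.92 ± 0.15. A difference taken relative to all genes already leaves out most of a shift shared by the genes of a library. The quantile value therefore adds little on scaling, and the 0.95 shows only that the lists differed beyond such a shift. Chance can be excluded for the count of zone calls over all genes, since of 100 splits only the real 1 gave as many as 6334, and the highest other gave 24. The splits did not take these lists or their direction by themselves. Zone labels exchanged cannot be told apart from a true difference between sections as they were taken. The labels are the only record of the zones used here, and the lists outside the pattern do not settle it. Of the 20 means of cell expansion, root hair, endodermal and xylem lists over the 5 ages, 15 lay on the side an exchange predicts. The other 5 lay on the side the labels give: all 4 lists at day 7 (by 0.04 to 0.80) and the endodermal list at day 5. These means were not taken relative to all genes. Medians of all tested genes at day 7 were 3.17 and 2.88 in the libraries labelled EZ and 2.68 and 2.39 in those labelled MZ. That gap is wider than the 0.04, 0.09 and 0.08 of the cell expansion, root hair and xylem lists, whose side is therefore open. At day 5 the medians were 3.11 and 3.26 in the libraries labelled EZ and 2.65 and 2.96 in those labelled MZ. That gap is close to the 0.39 of the endodermal list, whose side at day 5 is therefore open too. Of the root cap genes, RCPG, BRN1 and BRN2 were called on the side the labels give and FEZ on the other. BRN1 and BRN2 lost their calls in some fits that left out 1 library. The root cap list mean lay on the side the labels give at each of the 5 ages, by 0.04 to 0.39, though its median as deposited did not. The true difference stays open and untested, as does an exchange at the bench or in the column names.

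Most genes with an age trend in the libraries labelled MZ fell. The 188 with a known length had a median slope of -0.34 as deposited and -0.26 with the length trend removed, where 7 stayed called; their median length was 878 bp against 1624 bp for all tested genes. That removal also took out each library's overall shift. Scaling alone gave the 190 falling genes a median slope of -0.29, with 36 still called after quantile normalisation and 35 after median-of-ratios scaling. Transcript length and scaling may therefore each account for part of the pattern. They cannot be told apart from each other or from age, because the slopes kept most of their size while the calls were lost. Without the libraries of replicate 2 at days 6 and 7 the median slope of the falling genes was -0.34, with a median SE of 0.07 against 0.06. These genes were picked for their slope in data that hold the remaining libraries too. The value therefore cannot decide whether the libraries left out caused the pattern. In 2 of 100 splits as many genes were called, the real 1 included, a share under 0.05 for this count taken alone. Chance is not excluded by it, since splits for the other counts within a zone gave 7, 20 and 51 of 100. The highest other split here called 328, more than the real one, for a reason that was not tested. Age itself stays open.

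Genes whose zone difference changed with age were mostly listed at 0: 8 of the 10 were at 0 in at least 10 libraries, and 7 were above 0 only in the 2 replicates of 1 group. Values listed at 0 for short or weakly measured transcripts cannot be told apart from expression limited to a group, because nothing in the table separates a failed estimate from absence. Values above 0 falling independently in each library are open too: of 134 genes above 0 in exactly 2 libraries, 16 had them in replicates of a group, where 9.27 are expected (exact binomial, one-sided p 0.0233). A change with age in 1 zone stays open and untested.

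The limma test of a zone difference that changes among ages gave these adjusted p values. They were 0.000192 for AT3G54804, at 28.9 and 22.4 FPKM in the libraries labelled MZ of day 7 and at 0 elsewhere, and 0.000291 for AT3G01572, at 18.5 and 16.4 FPKM in those labelled EZ of day 7 and at 0 elsewhere. AT3G50764 (0.00376) was above 0 only in the libraries labelled EZ of days 5 and 6. AT2G23920 (0.00625), AT5G42405 (0.0134), AT3G28193 (0.0165) and AT5G50136 (0.0189) were above 0 only in those labelled EZ of day 6, and AT3G22723 (0.00668) only in those labelled MZ of day 4. The B3 domain gene AT2G31460 (0.0229) had its highest group means in the libraries labelled EZ of day 6, at 4.87 FPKM, and labelled MZ of day 3, at 2.83 FPKM. AT4G06477 (0.0305) fell in the libraries labelled MZ from 34.5 FPKM at day 3 to 2.58 FPKM at day 6 and reached 74.0 FPKM in those labelled EZ of day 6. AT2G23920, AT5G42405 and AT3G28193 lost these calls without MZ day 6 replicate 1 or MZ day 6 replicate 2 (highest adjusted p 0.131, 0.195 and 0.195), and AT5G50136, AT2G31460 and AT4G06477 in 4, 7 and 12 of the 20 fits that left out 1 library. The test of a trend of the zone difference gave adjusted p of 0.000781 for AT3G01572 and 0.000541 for AT3G54804.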

How the results depend on the processing

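Of the alternatives in this part, those that left out groups of libraries or used transcript length, and all for the trend averaged over both zones, were chosen after the data were seen. The zone count kept within 1.5 times of 6334 under every alternative except that without the 3 libraries of lowest depth (4177), which has fewer samples; leaving out 1 library gave 5222 to 6628. Of its calls, 4412 were shared after quantile normalisation and 4773 with the length trend removed. The age counts moved with nearly every choice, and where no reason is given the cause was not tested. Depth can limit the precision of weakly expressed genes, which was not tested. A group holds 2 libraries, and few age effects under 0.5 log2 per day were recoverable in simulated data. All genes named by the rule kept their direction under all alternatives run except SHY2, at -0.20 after quantile normalisation.

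With a pseudocount of 0.1 the counts were 0 for any change of the zone difference, 0 for its trend and 25 for the trend over both zones. With a pseudocount of 5 they were 25 for any age difference in EZ, 6 for the EZ trend, 5 for days 5 against 3 in MZ and 42 for days 7 against 5 in MZ. With no filter they were 241 and 178 for any age difference in MZ and EZ, 382 and 49 for the trends in MZ and EZ, 64 and 132 for days 5 against 3 and 7 against 5 in MZ, 21 for each of these pairs in EZ, 117 for any change of the zone difference, 57 for its trend and 232 for both zones. With a filter at 5 FPKM, which tests fewer genes, they were 1 each for any age difference, trend and days 5 against 3 in EZ, 0 for days 7 against 5 in EZ, 0 for either change of the zone difference and 120 for both zones.

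Quantile normalisation gave 41 for any age difference in MZ, 49 for the MZ trend and 23 for days 7 against 5 in MZ, and median-of-ratios scaling gave 38, 48 and 23 for these and 34 for both zones. Library weights gave 56 for any age difference in MZ, 14 for days 5 against 3 in MZ and 8 in EZ. Without the 4 libraries of replicate 2 at days 6 and 7, which leaves fewer samples, the counts were 26 for any age difference in MZ, 24 and 5 for the trends in MZ and EZ, 15 and 4 for days 5 against 3 in MZ and EZ, 5 for days 7 against 5 in EZ, 5 for the trend of the zone difference and 15 for both zones. Without the 2 libraries of replicate 2 at day 4 they were 40 for any age difference in MZ, 26 for its trend, 20 and 4 for days 7 against 5 in MZ and EZ, 5 for days 5 against 3 in EZ, 4 for the trend of the zone difference and 11 for both zones. Without the 3 libraries of lowest depth they were 39 for any age difference in MZ, 2 for its trend, 1 for days 5 against 3 and 7 for days 7 against 5 in MZ, 5 and 0 for any change and the trend of the zone difference, and 4 for both zones.

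With the length trend removed the counts were 6 and 4 for any age difference in MZ and EZ, 12 for the MZ trend, 4 and 1 for days 7 against 5 in MZ and EZ, 0 for days 5 against 3 in EZ, 1 and 0 for any change and the trend of the zone difference, and 24 for both zones. With transcripts of at least 300 bp, which tests fewer genes, they were 1 for any age difference in EZ, 36 and 0 for days 7 against 5 in MZ and EZ, 1 for days 5 against 3 in EZ, 0 for either change of the zone difference and 84 for both zones. Of the lists called by camera, 9 for the zones, 1 and 3 for the trends in MZ and EZ and 3 for the trend of the zone difference, an estimated correlation left 0 for each, and fry left 4 for the zones and 0 for the others.

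Leaving out each library in turn gave 2 to 132 for any age difference in MZ, 9 to 35 in EZ, 7 to 198 for the MZ trend, 2 to 31 for the EZ trend, 0 to 12 and 3 to 99 for days 5 against 3 and 7 against 5 in MZ, 1 to 5 and 2 to 20 for these in EZ, 4 to 22 and 2 to 9 for any change and the trend of the zone difference, and 7 to 267 for both zones. With the replicate number as a block, the zone count was 6636, and with blocks of age and number 7029. The number alone gave 116 and 12 for any age difference in MZ and EZ, 260 and 3 for the trends, 92 for days 7 against 5 in MZ and 225 for both zones, and age with number gave 1 and 0 for any change and the trend of the zone difference. Whether the numbers pair the samples is open: the correlation across genes of the replicate deviations between zones was 0.0775, 0.440, 0.0924, 0.0877 and 0.555 at days 3 to 7, and genes are not independent replicates.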

Other observations

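Of the tests in this part, those of the trend averaged over both zones were chosen after the results were seen, and the splits for ages within a zone were planned.

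Among genes with a trend averaged over both zones were AT1G50050, of the cysteine-rich secretory proteins, and AT5G43520, which rose by 0.79 ± 0.09 and 0.65 ± 0.08 log2 per day (SE, n = 20; limma adjusted p 0.00177 and 0.00747). AT5G43520 read 7.34 and 6.44 FPKM at day 3 and 53.2 and 82.4 FPKM at day 7 in the libraries labelled MZ, and 8.07 and 6.32 FPKM and then 54.2 and 85.5 FPKM in those labelled EZ. ACBP6 had a slope of -0.25 ± 0.04 (adjusted p 0.0168), of which -0.48 in the libraries labelled MZ and -0.03 in those labelled EZ. GA20OX5 had one of -0.82 ± 0.12 (0.0168), and these 2 lost their calls in 6 and 5 of the 20 fits that left out 1 library. In the libraries labelled EZ the heat shock protein family had a median slope of -0.17 log2 per day, with 0 of 37 genes called by limma and 3 adjusted over the list alone (camera adjusted p 3.13e-08, and adjusted p = 0.379 with an estimated correlation). At days 6 and 7 the family mean there was 4.123 and 4.275 in replicate 2, against 5.059 and 4.572 in replicate 1.

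The rising genes over both zones had a median slope of 0.39 (median SE 0.06) as deposited and 0.42 with the length trend removed. In the latter, 14 of 19 stayed called. That removal also took out each library's overall shift, and quantile normalisation alone gave 0.42 too. Transcript length is thus argued against only as the whole cause, and for genes picked by their slope in these data. For the falling genes transcript length may contribute and cannot be told apart from scaling or age. With the length trend removed 9 of 32 stayed called, although the median slope was -0.42 before and -0.39 after. Quantile normalisation alone gave -0.38. Of 100 splits only the real 1 gave as many as 54 calls for both zones, and the highest other gave 10. These splits cannot exclude chance, since the comparison was chosen after the data were seen. They also reordered the ages within each zone, while replicate deviations correlated between the zones at days 4 and 7 (0.440 and 0.555).

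For the other counts within a zone the splits gave less. In 7 of 100 splits as many as 92 genes differed between ages in the libraries labelled MZ (highest other 466, several times the real count, for a reason that was not tested). In 20 as many as 12 differed in those labelled EZ (highest other 24), and in 51 as many as 3 had a trend in those labelled EZ (highest other 29). Chance could not be excluded for these 3 counts.

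The first 3 principal components of the libraries held 27.8%, 13.1% and 7.5% of the variance. The second set apart replicate 2 of days 6 and 7 in both zones, and the third replicate 2 of day 4. The mean of the endodermal barrier list was 1.27 in EZ day 6 replicate 2, against 4.25 to 6.52 in the other libraries, and CASP1 read 4.93 FPKM there.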
